A study of Mus musculus with 16 samples.

How the data were processed

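Affymetrix mouse genome arrays measured total RNA of FACS-sorted thymic cells in 16 samples, per the labels. Titles and descriptions gave 8 groups of 2 samples and their numbers. The deposited table held 12488 probe sets, each with 1 linear intensity value per array. Every array had a 2%-trimmed mean of 100.1, as scaling of each array to a common target would give. The authors' software and its version are not given in the sources used here. The values were used as deposited because these means lay within the limit set before the data were examined. The lists, tests, named-gene rule and the alternatives not said to be added later were also fixed before the data were examined. No replicate pair held identical values. The number of arrays limits the precision. Replicates correlated across probe sets at a Pearson r of 0.921 and 0.918 in the knockout groups, 0.966 and 0.964 in the wild-type CD80-sorted groups and 0.896 to 0.942 in the others.

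A constant of 4.8, the 20th percentile of all values, was added before taking log2. The 66 control probe sets were left out, and 3103 others that did not exceed 17.3, the 40th percentile, on at least 2 arrays, which left 9319. In the annotation given 10833 probe sets had 1 gene symbol, 396 had several and 1193 had none listed. Symbols were updated through the GRCm38.p6 gene table for 10839 probe sets and kept for 16. That table served otherwise only for which genes neighbour each other. Of the tested probe sets, 8356 had 1 gene, for 6922 genes.

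Each comparison was a contrast in 1 limma model (3.58.1, R 4.3.3, with the data.table package 1.17.8) over all 16 arrays, with lmFit and eBayes with a trend (8 residual and 5.97 prior degrees of freedom). Tests were 2-sided and adjusted by Benjamini-Hochberg over the tested probe sets, with a threshold of 0.05 and no minimum fold. Rose, fell, higher and lower refer to this threshold. In all, 28 gene lists with 828 members, 564 of them measured, were tested with camera (correlation 0.01) on the brightest probe set per gene, adjusted over the lists of a comparison, and again with an estimated correlation. They covered MHC class II and costimulation, MHC class I and interferon, thymic, medullary and cortical epithelium, dendritic cells, macrophages, thymocytes, B cells, fibroblasts, endothelium and erythroid cells. Those of other tissues were liver and plasma proteins, pancreas, intestine and stomach, mammary gland, salivary and lacrimal gland, skin, nervous system and eye, muscle, testis and germ cells, endocrine genes, and lung and kidney. The others were earlier reported Aire targets, cell cycle, immediate early and stress genes, chemokines and cytokines, and ribosome and housekeeping genes. The alias Slc39a1 of Slc40a1 was excluded after the data were seen, since it is now the symbol of another gene.

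Named genes were, per comparison, the 6 highest and 6 lowest log2 fold changes past the threshold with 1 gene symbol that is not a clone name (brightest probe set per gene), the 2 members with the smallest p of each list past the list test, and Aire, Cd80, Ins2 and Gad1 among the CD80-sorted groups. Of 188 such genes, 27 rested on probe sets whose suffix marks probes shared with similar sequences. Shared-array overlaps were set against 100 simulations of unchanged groups, from which as many top-ranked probe sets were taken. Since nearly none of these passed the threshold, the simulated lists may overstate the part due to shared arrays. Neighbours within 200 kb were counted against 10000 random draws.

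The steps were tested on simulated data for the wild-type CD80hi and CD80lo comparison with 9319 probe sets. Of 50 planted changes each, 18%, 76%, 96% and 100% were recovered at log2 sizes of 1, 2, 3 and 4, and 4 of 149 calls were false. The list and neighbour steps recovered a planted list and planted neighbours. Alternatives were quantile normalisation, smaller (1) and larger (17.3) constants, no and a stricter (50) filter, eBayes without trend, only the groups compared, the replicate number as a block and each array left out. Further ones were the mean over a gene's probe sets, the estimated correlation, the fry test, other windows and 1 gene per family. Same-numbered unfractionated arrays deviated together, with a Pearson r across probe sets of 0.279 to 0.526 in all 6 pairs of groups. The alternatives added after seeing the data were a block for this array batch, inferred from the highest signals, a split of the shared wild-type CD80hi arrays, leaving out 324 bright probe sets, the fit without array 1 of both knockout groups and a block for the number of the knockout arrays.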

Results

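RNA from sorted cells of the mouse thymus was measured on 16 oligonucleotide arrays in 8 groups of 2. Medullary thymic epithelial cells (mTEC), which express genes of many other tissues, were sorted from wild-type and from Aire-knockout mice into a fraction with high (CD80hi) and a fraction with low (CD80lo) surface CD80, a costimulatory protein that increases as these cells mature. The other groups were unfractionated mTEC, cortical thymic epithelial cells (cTEC), thymic dendritic cells and thymic macrophages, all from wild-type mice. Aire is a transcriptional regulator that mTEC need for part of this expression. The 2 arrays per group limit the precision, and the labels do not say whether samples of a group came from separate animals. Each limma p-value rests on the spread pooled over all groups, which may be technical. Camera, Fisher and permutation p-values compare genes or probe sets, not samples. Fold changes are differences of log2(signal + 4.8) with the standard error of the fit after ±, which understates changes of dim genes. Signals are means with the standard deviation after ± (n = 2). List calls held with an estimated correlation unless a second p is given.

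Aire itself gave signals of 1829 and 1704 on the wild-type CD80hi arrays and 1589 and 1385 on the knockout CD80hi arrays. On the CD80lo arrays it gave 196 and 94.4 in wild type and 127 and 83.0 in knockout samples. Unfractionated mTEC gave 1386 and 2887, cTEC 37.8 and 113, dendritic cells 65.2 and 36.1, and macrophages 47.3 and 33.3. The Aire change between knockout and wild type was -0.25 ± 0.51 in CD80hi cells (adjusted p = 0.977) and -0.39 ± 0.51 in CD80lo cells (adjusted p = 0.999), both within the spread. The sources used here do not place this probe set relative to the deleted part, so its signal checks nothing about the genotype. Knockout means labelled as knockout throughout.

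**Figure D1:**
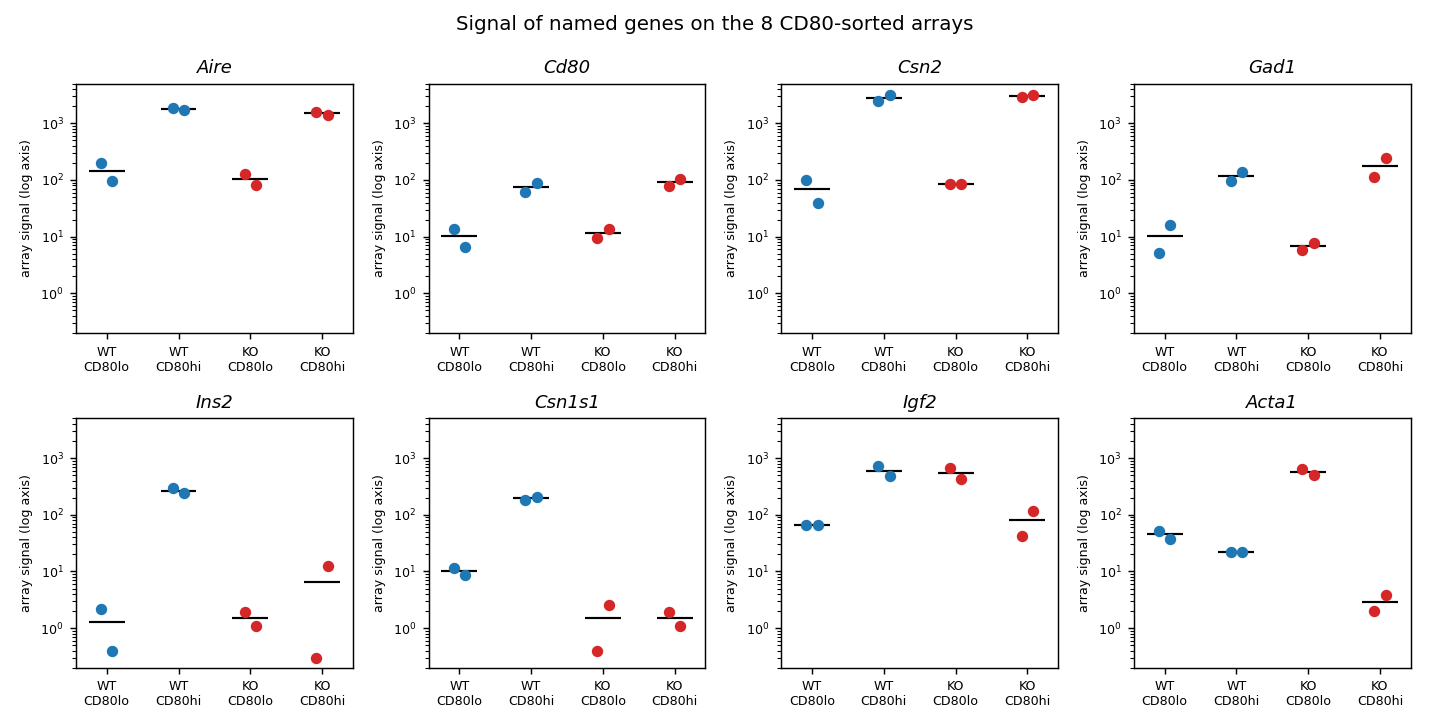
Array signal on a log axis (arbitrary units) of 8 named genes in the 4 CD80-sorted groups, with 1 point per array and a bar at the mean of the 2 arrays; blue is wild type (WT) and red knockout (KO). Aire, Cd80, Csn2 and Gad1 were higher in CD80hi than CD80lo samples of both genotypes, while Ins2 averaged 266 in wild-type CD80hi and 6.45 in knockout CD80hi samples.

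The first comparison asked how mature and less mature mTEC differ in wild-type mice. Fabp9, a fatty-acid-binding protein of the testis, had a signal of 1871 ± 240.1 in CD80hi and 11.7 ± 2.19 in CD80lo cells, a log2 fold change of 6.83 ± 0.53. The plasma apolipoproteins Apoa1 and Apoa4 rose by 5.54 ± 0.38 and 5.23 ± 0.55, the insulin gene Ins2 by 5.48 ± 0.50 and the milk protein gene Csn2 by 5.36 ± 0.55, with Csn2 reaching 2776 ± 443 in CD80hi cells. Gstm6, a glutathione transferase, rose by 5.29 ± 0.39. In the other direction lay Gas1, a membrane protein of growth arrest (-5.02 ± 0.55), the parathyroid hormone gene Pth (-4.46 ± 0.49), the immunoglobulin segment Igkv6-23 (-4.44 ± 0.77), the transcriptional inhibitor Id1 (-4.32 ± 0.38), the smooth-muscle protein gene Tagln (-4.30 ± 0.42) and the Notch ligand gene Jag2 (-4.27 ± 0.57).

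Most lists of genes of other tissues were higher in CD80hi cells. Of 30 liver and plasma protein genes, 16 rose and 14 did not pass (19 rose adjusted over the list alone, camera adjusted p = 2.98e-11). Of 25 intestine and stomach genes, 16 rose and 9 did not pass (20 rose adjusted over the list alone, camera adjusted p = 8.08e-15), with the keratin Krt20 at 4.82 ± 0.35 and the gut hormone Gip at 3.60 ± 0.35. Of 21 pancreas genes, 10 rose, 1 fell and 10 did not pass (12 rose and 1 fell adjusted over the list alone, camera adjusted p = 3.19e-06), including the pancreatic polypeptide gene Ppy (1.92 ± 0.32). Of 7 mammary gland genes, 5 rose and 2 did not pass (5 rose adjusted over the list alone, camera adjusted p = 3.22e-07), including the casein gene Csn1s2a (4.33 ± 0.38). Of 8 salivary and lacrimal gland genes, 5 rose and 3 did not pass (5 rose adjusted over the list alone, camera adjusted p = 0.000362), among them the kallikreins Klk1b22 (3.30 ± 0.34) and Klk1b9 (2.63 ± 0.35). Both rested on probe sets whose suffix marks probes shared with similar sequences. Counts and tests of this list may thus repeat a signal, in every comparison. Of 32 nervous system and eye genes, 14 rose and 18 did not pass (18 rose adjusted over the list alone, camera adjusted p = 1.69e-07), with Pomc, a peptide hormone precursor, at 3.12 ± 0.36, the calcium-binding Calb1 at 3.30 ± 0.42 and Gad1, a GABA-synthesising enzyme, at 3.07 ± 0.62.

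Of 23 endocrine genes, 12 rose, 1 fell and 10 did not pass (14 rose and 1 fell adjusted over the list alone, camera adjusted p = 1.34e-05), Pth being the gene that fell. Of 17 testis and germ cell genes, 6 rose and 11 did not pass (7 rose adjusted over the list alone, camera adjusted p = 0.000499), including the egg-coat gene Zp3 (3.15 ± 0.43). Of 34 muscle genes, 11 rose and 23 did not pass (14 rose and 4 fell adjusted over the list alone, camera adjusted p = 0.00132, but adjusted p = 0.0888 with an estimated correlation), with the myosins Myh4 (3.90 ± 0.39) and Myl7 (4.11 ± 0.53). Of 28 skin genes, 11 rose, 1 fell and 16 did not pass (16 rose and 1 fell adjusted over the list alone, camera adjusted p = 7.67e-07, but adjusted p = 0.0888 with an estimated correlation), among them Klk6 (3.31 ± 0.38) and Krt16 (3.01 ± 0.45). Of 12 lung and kidney genes, 3 rose and 9 did not pass (7 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.00287, but adjusted p = 0.0736 with an estimated correlation), with the airway secretoglobin Scgb1a1 at 2.43 ± 0.43. Of 9 erythroid genes, 3 rose and 6 did not pass (5 rose adjusted over the list alone, camera adjusted p = 0.000447), with the membrane protein gene Epb42 at 3.14 ± 0.47. Of 13 earlier reported Aire targets, 11 rose and 2 did not pass (12 rose adjusted over the list alone, camera adjusted p = 2.32e-13). That list was written from general knowledge of Aire studies, which can include work on these samples, so it is not independent evidence. Across all lists, 29 genes stood in more than 1 list.

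Of 16 MHC class II and costimulation genes, 6 rose and 10 did not pass (6 rose adjusted over the list alone, camera adjusted p = 2.41e-05), with the lysosomal protease Ctsh at 2.83 ± 0.43. Cd80, the marker used for the sort and hence no finding, gave 2.43 ± 0.37. Of 17 medullary epithelium genes, 9 rose and 8 did not pass (11 rose adjusted over the list alone, camera adjusted p = 7.6e-07, but adjusted p = 0.0522 with an estimated correlation), with Aire at 3.65 ± 0.51. Of 39 chemokine and cytokine genes, 12 rose, 3 fell and 24 did not pass (14 rose and 6 fell adjusted over the list alone, camera adjusted p = 0.037, but adjusted p = 0.241 with an estimated correlation), with the chemokine Ccl9 at 4.46 ± 0.33 and Tnf at 4.89 ± 0.41. Of 23 immediate early and stress genes, 1 rose, 9 fell and 13 did not pass (1 rose and 13 fell adjusted over the list alone, camera adjusted p = 7.67e-07), including the transcription factors Jun (-2.42 ± 0.32) and Egr2 (-2.20 ± 0.31). Of 20 MHC class I and interferon genes, 4 fell and 16 did not pass (5 fell adjusted over the list alone, camera adjusted p = 0.0206, but adjusted p = 0.0888 with an estimated correlation), with Gbp2 (-2.21 ± 0.29) and Ifit3 (-3.65 ± 0.51). The cell cycle and ribosome and housekeeping lists fell by camera (adjusted p = 0.000102 and 0.0299), but not past the threshold with an estimated correlation (adjusted p = 0.207 and 0.241). Quantile normalisation ended the chemokine and ribosome calls.

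Markers of other cells that a sort can carry along also moved. Of 18 fibroblast genes, 6 fell and 12 did not pass (8 fell adjusted over the list alone, camera adjusted p = 0.000745, but adjusted p = 0.0888 with an estimated correlation), with the collagens Col6a2 (-3.05 ± 0.38) and Col6a1 (-2.91 ± 0.36). Of 12 endothelium genes, 4 fell and 8 did not pass (6 fell adjusted over the list alone, camera adjusted p = 0.000499, but adjusted p = 0.199 with an estimated correlation), with the adhesion molecule Selp at -3.99 ± 0.68. Of 29 macrophage genes, 4 rose and 25 did not pass (5 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.00524, but adjusted p = 0.226 with an estimated correlation), with the lysozyme gene Lyz2 at 3.79 ± 0.45. Of 19 dendritic cell genes, 3 rose and 16 did not pass (4 rose adjusted over the list alone, camera adjusted p = 0.00443, but adjusted p = 0.189 with an estimated correlation), with the transcription factor Irf4 at 2.49 ± 0.41. The thymic epithelium, cortical epithelium, thymocyte and B cell lists did not pass (camera adjusted p = 0.824, 0.611, 0.824 and 0.293).

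Of the 9319 probe sets tested with limma, 744 were higher and 442 lower in wild-type CD80hi than CD80lo cells, and 2221 had an unadjusted p under 0.05. By camera 24 of the 28 lists passed, and 12 kept the call with an estimated correlation. The 1186 calls became 626 or 631 without CD80hi array 1 or 2, 681 or 627 without CD80lo array 1 or 2, and 2456 when only these groups were fitted. Gad1 lost its call without CD80hi array 2 or CD80lo array 1 (adjusted p up to 0.0618).

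The second comparison asked which transcripts of mature mTEC depend on the Aire genotype, by setting knockout against wild-type CD80hi cells. The casein gene Csn1s1 fell from 194 ± 11.9 to 1.5 ± 0.566, a log2 fold change of -4.98 ± 0.39, and the protease Ctse from 3797 ± 196 to 153 ± 135 (-4.91 ± 0.47). Ins2 fell to 6.45 ± 8.7 (-4.84 ± 0.50), the mucin-like Mucl2 to 7.6 ± 9.48 (-4.47 ± 0.54), Csn1s2a to 2.25 ± 0.495 (-4.13 ± 0.38) and the gut hormone cholecystokinin, Cck, to 0.9 ± 0.424 (-4.10 ± 0.32). Few genes rose, and those the naming rule admits included Ccnb1ip1, a meiotic recombination factor (4.17 ± 0.60), the Y-linked Eif2s3y (3.92 ± 0.67), Fut1 (2.10 ± 0.46), Serpini1 (1.87 ± 0.45), Cdca7l (1.75 ± 0.38) and the myosin Myh7 (1.59 ± 0.37). Gad1 had a log2 fold change of 0.51 ± 0.62 (adjusted p = 0.915) and Cd80 0.30 ± 0.37 (adjusted p = 0.922), both within the spread.

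Of 8 salivary and lacrimal gland genes, 5 fell and 3 did not pass (6 fell adjusted over the list alone, camera adjusted p = 3.39e-08), including Klk1b22 (-3.18 ± 0.34) and Klk1b9 (-2.30 ± 0.35). Of 7 mammary gland genes, 3 fell and 4 did not pass (4 fell adjusted over the list alone, camera adjusted p = 8.94e-06). Of 21 pancreas genes, 8 fell and 13 did not pass (15 fell adjusted over the list alone, camera adjusted p = 7.26e-13), with the secretory granule protein Chgb at -3.14 ± 0.42. Of 30 liver and plasma protein genes, 13 fell and 17 did not pass (17 fell adjusted over the list alone, camera adjusted p = 8.76e-14), with Apoa1 at -2.87 ± 0.38 and the fibrinogen chain Fgb at -2.33 ± 0.38. Of 23 endocrine genes, 6 fell and 17 did not pass (12 fell adjusted over the list alone, camera adjusted p = 8.85e-07). Of 25 intestine and stomach genes, 7 fell and 18 did not pass (9 fell adjusted over the list alone, camera adjusted p = 3.44e-11), with Gip at -3.00 ± 0.35. Of 9 erythroid genes, 2 fell and 7 did not pass (2 fell adjusted over the list alone, camera adjusted p = 0.00253), namely Car2 (-1.87 ± 0.32) and Rhd (-1.73 ± 0.40). Of 12 lung and kidney genes, 2 fell and 10 did not pass (3 fell adjusted over the list alone, camera adjusted p = 0.000709), namely Slc12a3 (-3.03 ± 0.42) and Scgb1a1 (-1.98 ± 0.43).

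Of 34 muscle genes, 1 rose, 5 fell and 28 did not pass (1 rose and 9 fell adjusted over the list alone, camera adjusted p = 1.25e-05), with Actc1 (-1.84 ± 0.29) and Chrna1 (-2.26 ± 0.39) falling and Myh7 rising. Of 17 testis and germ cell genes, 5 fell and 12 did not pass (5 fell adjusted over the list alone, camera adjusted p = 0.0082), including Zp3 (-2.63 ± 0.43) and Ldhc (-2.24 ± 0.37). Of 28 skin genes, 3 fell and 25 did not pass (10 fell adjusted over the list alone, camera adjusted p = 1.32e-06, but adjusted p = 0.118 with an estimated correlation), among them Klk6 (-3.37 ± 0.38) and Sprr2f (-2.80 ± 0.56). Of 32 nervous system and eye genes, 4 fell and 28 did not pass (10 fell adjusted over the list alone, camera adjusted p = 1.55e-05, but adjusted p = 0.0637 with an estimated correlation), with Pomc (-2.62 ± 0.36) and Penk (-2.83 ± 0.41). The mean over all Penk probe sets ended the Penk call. Of 39 chemokine and cytokine genes, 2 fell and 37 did not pass (4 fell adjusted over the list alone, camera adjusted p = 0.0129, but adjusted p = 0.233 with an estimated correlation), namely Ccl8 (-2.37 ± 0.47) and Ccl9 (-1.56 ± 0.33). Of 13 earlier reported Aire targets, 8 fell and 5 did not pass (12 fell adjusted over the list alone, camera adjusted p = 1.34e-16), with the calprotectin subunit S100a9 at -3.62 ± 0.46, a list that is not independent evidence.

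Of 16 MHC class II and costimulation genes, limma called 0, with 2 higher and 0 lower at an unadjusted p under 0.05 (likewise 0 adjusted over the list alone, camera adjusted p = 0.00012), with H2-Ob at 1.57 ± 0.50 and Cd83 at 0.94 ± 0.35. The cell cycle and ribosome and housekeeping lists were higher by camera (adjusted p = 0.00722 and 0.0396), but not past the threshold with an estimated correlation (adjusted p = 0.461 and 0.346). The cell cycle median was 0.71 between the first arrays and -0.08 between the second, and quantile normalisation, which moved the median of all probe sets by 0.11, ended the ribosome call. The fibroblast, endothelium, macrophage, dendritic cell, thymocyte and B cell lists did not pass (camera adjusted p = 0.383, 0.622, 0.183, 0.622, 0.0957 and 0.594).

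Limma called 16 probe sets higher and 268 lower in knockout than wild-type CD80hi cells, with 1076 at an unadjusted p under 0.05. Quantile normalisation gave 235 lower, with 10.3% of calls higher against 5.63%. By camera 17 of the 28 lists passed, and 12 of them kept the call with an estimated correlation. The 18S ribosomal control, not used in any comparison, read 562 on the first knockout CD80hi array, 48.2 on the second and 148 and 159 on the wild-type ones. Without array 1 of both knockout groups, a fit chosen after seeing the data, 157 probe sets passed, against 284. The count was 145 without knockout array 1 and 88 or 81 without wild-type array 1 or 2, and 180 with the smaller constant. Fut1, Cdca7l and Rhd lost their calls without any of these 4 arrays (adjusted p up to 0.224, 0.278 and 0.304). Myh7, Sprr2f, Scgb1a1 and Ccl9 lost their calls without knockout array 1 or either wild-type array (adjusted p up to 0.371, 0.162, 0.288 and 0.224). Serpini1 lost its call without knockout array 2 or either wild-type array (adjusted p up to 0.366) and Ccl8 lost its call without array 1 of either genotype (adjusted p up to 0.206). Chrna1 lost its call without either wild-type array (adjusted p up to 0.0552), Zp3 lost its call without wild-type array 1 (adjusted p up to 0.0554) and Eif2s3y, Car2, Fgb, Actc1 and Ldhc lost their calls without wild-type array 2 (adjusted p up to 0.0571, 0.0706, 0.0552, 0.0536 and 0.0631).

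Ins2, Csn1s2a, Apoa1, Gip and Klk1b22 were both raised in wild-type CD80hi and lower in knockout CD80hi cells. In all, 202 of the 268 probe sets lower in knockout CD80hi cells were among the 744 raised in wild-type CD80hi cells, against 21.4 for independent lists. Both comparisons used the wild-type CD80hi arrays, and lists of these sizes from 100 simulated sets of unchanged groups shared 111 ± 7.92 (SD). Part of the excess may come from the shared arrays. With 1 of them used for each comparison, a split chosen after seeing the data in which the lone array is assumed to vary like the others, 63 of 80 or 62 of 85 were shared, against 3.67 and 3.97 for independent lists. Across probe sets, which are not independent, the fold changes had a Pearson r of -0.342, against -0.502 simulated. Their covariance was -0.237, against -0.109 simulated, a difference of -0.129, and -0.188 or -0.179 with the split. Across the CD80hi-raised probe sets, chosen on arrays that the knockout change also uses, the median of that change was -0.82 in CD80hi cells (quartiles -1.84 and -0.02), against -0.41 (quartiles -0.70 and -0.14) in the simulated unchanged groups and -1.05 or -0.98 with the split. In CD80lo cells it was 0.10 (quartiles -0.23 and 0.48), against 0.41 simulated. The overlap was 114 with the smaller constant, 100 without knockout CD80hi array 1, and 63 or 65 without wild-type CD80hi array 1 or 2.

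A further overlap asked whether genes lower in knockout CD80hi cells are those that separate mTEC from cTEC, in arrays that the comparisons do not share. Of the 268 lower probe sets, 222 were among the 1038 higher in mTEC than cTEC, against 29.9 for independent lists (odds ratio 48.6, confidence interval 35.0 to 68.9, p = 5.81e-172 by a 2-sided Fisher's exact test over probe sets, which are not independent). Chgb, Csn1s1, Csn1s2a, Ins2 and Klk1b22 were in both. With the smaller constant the odds ratio was 45.2, and 82.0% of the 172 lower probe sets were shared, against 82.8%, while the count shared with mTEC-raised probe sets was lower by over 1.5 times. That count was 115 without knockout CD80hi array 1, and 78 or 73 without wild-type CD80hi array 1 or 2.

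The same genotype comparison in CD80lo cells gave few changes, most of them upward. The imprinted noncoding RNA Meg3 rose from 5.8 ± 0.141 to 212 ± 103, a log2 fold change of 4.27 ± 0.43, and the skeletal actin Acta1 from 44.9 ± 10.7 to 572 ± 90.7 (3.55 ± 0.32). The ephrin receptor Epha2 (3.52 ± 0.41), the glutathione transferase Gsto1 (3.37 ± 0.35), the iron-binding milk and neutrophil protein lactoferrin, Ltf (3.07 ± 0.56), and the imprinted growth factor Igf2 (2.93 ± 0.43) also rose. Ctse fell from 828 ± 187 to 48 ± 5.59 (-3.97 ± 0.47), while the others of its 3 probe sets gave -2.70 ± 0.33, also called, and 0.19 ± 0.58, not called. Ins2, at 1.5 ± 0.566 against 1.3 ± 1.27, differed by 0.06 ± 0.50 (adjusted p = 0.999), and Gad1 by -0.31 ± 0.62 (adjusted p = 0.999), both within the spread.

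Of 34 muscle genes, 4 rose and 30 did not pass (13 rose adjusted over the list alone, camera adjusted p = 7.55e-15), with the myosin light chain Myl1 at 2.51 ± 0.35. Of 28 skin genes, 1 rose and 27 did not pass (5 rose adjusted over the list alone, camera adjusted p = 0.00898, but adjusted p = 0.546 with an estimated correlation), namely Krt6a (2.89 ± 0.38). The thymic epithelium list was higher by camera (adjusted p = 0.00519). The cell cycle, MHC class I and interferon, dendritic cell and endothelium lists were lower by camera (adjusted p = 0.0013, 0.0216, 0.0434 and 0.00542). With an estimated correlation none passed (adjusted p = 0.377 for MHC class I and interferon and 0.546 for the others). Between the first and between the second arrays the skin median was -0.33 and 0.47, and the endothelium median -1.69 and 0.49. The pancreas, mammary gland and salivary and lacrimal gland lists, lower in knockout CD80hi cells, did not pass here (camera adjusted p = 0.801, 0.788 and 0.233).

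Of the 9319 probe sets, 26 were higher and 4 lower in knockout than wild-type CD80lo cells by limma, with 517 at an unadjusted p under 0.05, and of the 7 lists past the camera threshold 1, muscle, kept the call with an estimated correlation. The 18S control read 1893 and 287 on the knockout arrays and 342 and 376 on the wild-type ones, and 20 probe sets passed without array 1 of both knockout groups. The count was 19 without knockout array 1, 11 or 8 without wild-type array 1 or 2, 18 with the smaller and 47 with the larger constant, and 16 when only these groups were fitted. Ltf lost its call without any of the 4 arrays (adjusted p up to 0.359), Igf2 and Myl1 lost their calls without knockout array 1 or either wild-type array (adjusted p up to 0.119 and 0.0872) and Krt6a lost its call without wild-type array 2 (adjusted p up to 0.0758).

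The difference between the genotype effects of CD80hi and CD80lo cells was tested itself, as an interaction. Igf2 had the most negative value among named genes (-5.90 ± 0.61), with a signal of 599 ± 167 in wild-type and 79.7 ± 53.5 in knockout CD80hi cells but 66 ± 1.13 and 549 ± 172 in the CD80lo cells. Acta1 (-5.35 ± 0.45), Ltf (-5.06 ± 0.79), the epithelial keratin Krt19 (-4.70 ± 0.64) and Gsto1 (-4.48 ± 0.50) likewise had a more negative genotype effect in CD80hi cells. For Ins2 the difference was -4.90 ± 0.71, for Cck -4.41 ± 0.46, for Csn1s2a -4.22 ± 0.54 and for Zp3 -4.09 ± 0.61. In wild-type CD80lo cells Ins2, Csn1s2a and Zp3 read 1.3, 1.35 and 2, too dim to show a fall, and Cck 35.9. Aire (0.14 ± 0.72, adjusted p = 1.0), Cd80 (0.14 ± 0.53, adjusted p = 1.0) and Gad1 (0.82 ± 0.88, adjusted p = 1.0) did not pass, and a second Cd80 probe set had the opposite sign.

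In the groups, more negative means a lower genotype effect in CD80hi than in CD80lo cells. Of 34 muscle genes, 8 were more negative and 26 did not pass (15 more negative adjusted over the list alone, camera adjusted p = 4.29e-16), including Actc1 (-3.12 ± 0.41). Of 8 salivary and lacrimal gland genes, 3 were more negative and 5 did not pass (6 more negative adjusted over the list alone, camera adjusted p = 5.91e-09), with Klk1b22 (-3.19 ± 0.48) and Bpifa2 (-3.45 ± 0.69). Of 7 mammary gland genes, 3 were more negative and 4 did not pass (4 more negative adjusted over the list alone, camera adjusted p = 1.14e-06), with Csn1s1 at -3.72 ± 0.55. Of 21 pancreas genes, 2 were more negative and 19 did not pass (9 more negative adjusted over the list alone, camera adjusted p = 1.05e-10), namely Ins2 and Chgb (-2.62 ± 0.60). Of 25 intestine and stomach genes, 3 were more negative and 22 did not pass (6 more negative adjusted over the list alone, camera adjusted p = 1.09e-07), including Gip (-3.24 ± 0.50). Of 30 liver and plasma protein genes, 2 were more negative and 28 did not pass (1 more positive and 14 more negative adjusted over the list alone, camera adjusted p = 3.02e-09), namely Rbp4 (-3.29 ± 0.55) and Apoa1 (-3.08 ± 0.54). Of 23 endocrine genes, 3 were more negative and 20 did not pass (7 more negative adjusted over the list alone, camera adjusted p = 7.49e-07). Of 17 testis and germ cell genes, 2 were more negative and 15 did not pass (3 more negative adjusted over the list alone, camera adjusted p = 0.00867), namely Zp3 and Ldhc (-2.45 ± 0.53). Of 13 earlier reported Aire targets, 3 were more negative and 10 did not pass (7 more negative adjusted over the list alone, camera adjusted p = 1.05e-10), a list that is not independent evidence.

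Of 16 MHC class II and costimulation genes, limma called 0, with 2 higher and 0 lower at an unadjusted p under 0.05 (likewise 0 adjusted over the list alone, camera adjusted p = 5.68e-05). Of 28 skin genes, 4 were more negative and 24 did not pass (6 more negative adjusted over the list alone, camera adjusted p = 1.37e-09, but adjusted p = 0.0646 with an estimated correlation), including Klk6 (-3.27 ± 0.54) and Krt6a (-3.22 ± 0.54). The nervous system and eye, erythroid, lung and kidney, thymic epithelium, chemokine and cytokine and macrophage lists were more negative by camera (adjusted p = 9.19e-05, 0.0136, 0.00918, 0.000532, 0.038 and 0.0129), but not past the threshold with an estimated correlation (adjusted p = 0.0943, 0.0943, 0.105, 0.191, 0.30 and 0.304). The endothelium and cell cycle lists were more positive by camera (adjusted p = 0.0134 and 2.67e-06), but not past the threshold with an estimated correlation (adjusted p = 0.344 and 0.181). Rhd (-2.69 ± 0.57), a red-cell surface protein gene, Krt19 and Tnf (-2.63 ± 0.57) were the called members of the erythroid, thymic epithelium and chemokine lists. The endothelium median was 1.40 from the first arrays and -0.34 from the second.

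By camera 19 of the 28 lists passed, and 10 kept the call with an estimated correlation. The limma interaction passed for 121 probe sets, all more negative, with 775 at an unadjusted p under 0.05. The count was 69 without knockout CD80hi array 1, 60 without knockout CD80lo array 1, 34 without wild-type CD80hi array 1, 42 without wild-type CD80hi array 2, 68 without wild-type CD80lo array 1, 37 without wild-type CD80lo array 2, 79 without unfractionated mTEC array 1 and 79 without unfractionated mTEC array 2. It was 44 with the smaller and 216 with the larger constant, 77 when only the sorted mTEC were fitted, and 44 without array 1 of both knockout groups. Ldhc lost its call without any of the 8 sorted arrays (adjusted p up to 0.174), and Rhd and Chgb lost their calls without any of them but knockout CD80lo array 2 (adjusted p up to 0.168 and 0.227). Bpifa2 lost its call without any but knockout CD80lo array 1 (adjusted p up to 0.121) and Tnf lost its call without any but knockout CD80hi array 1 (adjusted p up to 0.222). Apoa1 lost its call without array 1 of either knockout group, wild-type CD80hi array 1 or wild-type CD80lo array 2 (adjusted p up to 0.0922). Klk6 and Krt6a lost their calls without wild-type CD80hi array 1 or CD80lo array 2 (adjusted p up to 0.0584 and 0.0663) and Rbp4 lost its call without wild-type CD80hi array 2 (adjusted p up to 0.0525).

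Knockout CD80hi and CD80lo cells were compared to ask which maturation differences are seen without wild-type Aire. Fabp9 rose by 5.50 ± 0.53, the acute-phase gene Saa3 by 5.40 ± 0.77, Csn2 by 5.06 ± 0.55, the gap junction gene Gjb2 by 4.74 ± 0.33, and the cytokines Il4 and Il13 by 4.76 ± 0.50 and 4.70 ± 0.45. Lower in CD80hi cells were Pth (-6.84 ± 0.49), Acta1 (-6.22 ± 0.32), Krt19 (-5.24 ± 0.45), the interferon-induced Ifit3 (-5.22 ± 0.51), Id1 (-5.15 ± 0.38) and the tissue factor gene F3 (-4.67 ± 0.46). Aire (3.79 ± 0.51), Cd80 (2.56 ± 0.37) and Gad1 (3.89 ± 0.62) rose, while Ins2 differed by 0.58 ± 0.50 (adjusted p = 0.549), within the spread.

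Of 16 MHC class II and costimulation genes, 10 rose and 6 did not pass (12 rose adjusted over the list alone, camera adjusted p = 3.87e-10), with Cd40 (2.59 ± 0.31) and Ctsh (3.43 ± 0.43). Of 25 intestine and stomach genes, 8 rose, 1 fell and 16 did not pass (9 rose and 1 fell adjusted over the list alone, camera adjusted p = 7.17e-05), with Krt20 (4.31 ± 0.35) and Cck (-3.14 ± 0.32). Of 30 liver and plasma protein genes, 7 rose, 3 fell and 20 did not pass (7 rose and 4 fell adjusted over the list alone, camera adjusted p = 0.0366, but adjusted p = 0.362 with an estimated correlation), with the antithrombin gene Serpinc1 at 3.09 ± 0.39 and the retinol carrier Rbp4 at -3.38 ± 0.39. Of 34 muscle genes, 2 rose, 10 fell and 22 did not pass (5 rose and 13 fell adjusted over the list alone, camera adjusted p = 0.00854, but adjusted p = 0.281 with an estimated correlation), including Actc1 (-3.12 ± 0.29). Of 23 immediate early and stress genes, 9 fell and 14 did not pass (1 rose and 16 fell adjusted over the list alone, camera adjusted p = 3.24e-06, but adjusted p = 0.0675 with an estimated correlation), with Ier3 (-3.63 ± 0.54) and Myc (-1.83 ± 0.31). Of 18 fibroblast genes, 7 fell and 11 did not pass (7 fell adjusted over the list alone, camera adjusted p = 0.00331, but adjusted p = 0.281 with an estimated correlation), with Col6a1 (-3.27 ± 0.36) and Col6a2 (-3.09 ± 0.38). Of 19 dendritic cell genes, 7 rose and 12 did not pass (7 rose adjusted over the list alone, camera adjusted p = 0.000436, but adjusted p = 0.281 with an estimated correlation), with Irf4 (3.46 ± 0.41) and Cd83 (2.08 ± 0.35). The medullary epithelium, nervous system and eye and earlier reported Aire target lists rose by camera (adjusted p = 0.000436, 0.0368 and 0.0136). The thymic epithelium list fell by camera (adjusted p = 0.00854). With an estimated correlation none passed (adjusted p = 0.281, 0.415, 0.362 and 0.408). The nervous system and eye median was -0.01 between the first and 0.40 between the second arrays. The pancreas, mammary gland, salivary and lacrimal gland and testis and germ cell lists did not pass here (camera adjusted p = 0.772, 0.478, 0.478 and 0.262), and each passed in the interaction.

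Between knockout CD80hi and CD80lo cells 553 probe sets were higher and 640 lower by limma, with 2292 at an unadjusted p under 0.05. By camera 11 of the 28 lists passed, and 2 kept the call with an estimated correlation. Of the 744 probe sets raised in wild-type CD80hi cells, 325 were also among the 553 raised in knockout ones, against 44.1 for independent lists and 54.9 ± 6.6 (SD) for simulated unchanged groups. The count of calls was 747 without CD80hi array 2, 744 without CD80lo array 1, 629 when only these groups were fitted and 532 without array 1 of both groups.

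**Figure D2:**
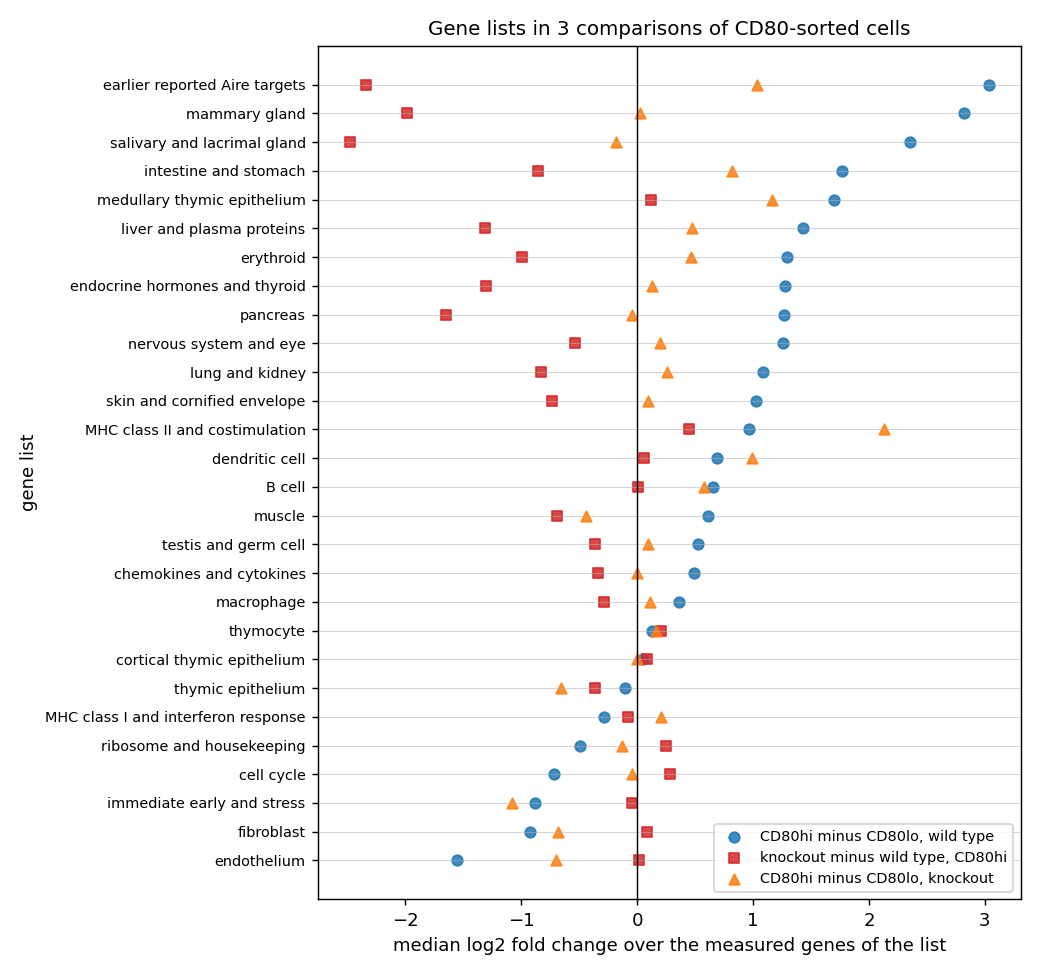
Median log2 fold change over the measured genes of each of the 28 gene lists, with circles for CD80hi minus CD80lo in wild type, squares for knockout minus wild type in CD80hi cells and triangles for CD80hi minus CD80lo in knockout samples. The salivary and lacrimal gland list stood at 2.36, -2.48 and -0.19 in these comparisons, and the MHC class II and costimulation list at 0.96, 0.45 and 2.13.

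Caseins (Csn1s1, Csn1s2a, Csn2) and kallikreins (Klk1b9, Klk1b22) lie in gene clusters, so it was asked whether called genes neighbour each other more often than tested genes drawn at random. Of 595 genes raised in wild-type CD80hi cells, 229 had another such gene within 200 kb, against a mean of 157 in 10000 draws (permutation p = 1e-04, the smallest these draws can give). For the 207 genes lower in knockout CD80hi cells the count was 62 against 22.1 (permutation p = 1e-04, again the smallest possible). With 1 gene kept per family of like-named neighbours, 136 of 508 CD80hi-raised genes had a called neighbour against 115 (permutation p = 0.0563), which no longer passed the threshold, and 21 of 150 knockout-lowered genes against 11.7 (permutation p = 0.0326).

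The remaining comparisons set unfractionated wild-type mTEC against other thymic cells. Their arrays fell into batches, since the highest signal was 2518 to 3524 on the first array of each of these groups and 4788 to 5630.0 on the second, and the ratio of 3′ to 5′ Gapdh control signal was 3.88 to 7.45 and 15.7 to 26.2. Each group had 1 array in each batch, so a batch block leaves each fold change as it is. The batch block was chosen after seeing the data, and correlations across probe sets are not over independent replicates.

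The comparison with cTEC asked what separates the epithelial cells of medulla and cortex. Higher in mTEC were the tight-junction gene Cldn7 (761 ± 541 against 3.9 ± 0.424, a log2 fold change of 6.25 ± 0.45), Fabp9 (5.88 ± 0.53), Saa3 (5.71 ± 0.77), the antimicrobial lectin gene Reg3g (5.53 ± 0.69), Avil (5.44 ± 0.48) and the kallikrein Egfbp2 (5.44 ± 0.45). Lower were the T-cell coreceptor gene Cd8b1 (-4.88 ± 0.57), the recombinase gene Rag1 (-4.64 ± 0.77), the chemokine Cxcl12 (-4.40 ± 0.59), Inmt (-4.15 ± 0.56), Kcnk2 (-4.03 ± 0.57) and the aminopeptidase Enpep (-3.78 ± 0.59). A second probe set of Rag1 and of Enpep had the opposite sign.

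Among 17 medullary epithelium genes, 12 were higher, 1 lower and 4 did not pass (12 higher and 1 lower adjusted over the list alone, camera adjusted p = 7.21e-09), with Cldn3 (3.89 ± 0.40) and Pigr (3.76 ± 0.39). Medians were 3.46 and 2.15 within the batches. Among 13 cortical epithelium genes, 4 were lower and 9 did not pass (4 lower adjusted over the list alone, camera adjusted p = 0.000203), including Cxcl12 and Cd83 (-2.67 ± 0.35). Medians were -0.90 and -1.77 within the batches. Among 19 thymocyte genes, 14 were lower and 5 did not pass (16 lower adjusted over the list alone, camera adjusted p = 1.1e-11), including Cd8b1 and Rag1. Medians were -2.22 and -2.61 within the batches. Among 39 chemokine and cytokine genes, 16 were higher, 1 lower and 22 did not pass (16 higher and 1 lower adjusted over the list alone, camera adjusted p = 8.89e-05), with Ccl9 (5.39 ± 0.33) and Tnf (4.90 ± 0.41). Medians were 0.75 and 0.88 within the batches. Among 25 intestine and stomach genes, 17 were higher and 8 did not pass (20 higher adjusted over the list alone, camera adjusted p = 4.05e-15), with Krt20 at 5.08 ± 0.35 and the microvillus gene Vil1 at 4.83 ± 0.36. Medians were 2.0 and 2.19 within the batches. Among 30 liver and plasma protein genes, 18 were higher and 12 did not pass (21 higher adjusted over the list alone, camera adjusted p = 1.63e-11), with Apoa1 (4.72 ± 0.38) and Apoa4 (5.42 ± 0.55). Medians were 1.52 and 1.85 within the batches. Among 21 pancreas genes, 12 were higher and 9 did not pass (16 higher adjusted over the list alone, camera adjusted p = 3.15e-09), with the islet peptide gene Iapp at 3.51 ± 0.37 and Chgb at 3.95 ± 0.42. Medians were 1.38 and 1.90 within the batches. Among 28 skin genes, 16 were higher and 12 did not pass (20 higher adjusted over the list alone, camera adjusted p = 2.04e-10), with Sprr1a (4.73 ± 0.39) and Klk6 (3.38 ± 0.38). Medians were 1.46 and 1.5 within the batches. The muscle, mammary gland, salivary and lacrimal gland, nervous system and eye, testis and germ cell, endocrine, lung and kidney, erythroid, MHC class II and costimulation and earlier reported Aire target lists were higher too (camera adjusted p = 2.31e-08, 1.69e-06, 0.000487, 9.51e-06, 0.00325, 1.07e-06, 4.4e-05, 0.000954, 0.0155 and 7.07e-12, with medians of 1 sign in both batches). By camera the dendritic cell list was higher and the cell cycle list lower (adjusted p = 0.00779 and 2.17e-07). Each had medians of 1 sign in both batches. Neither passed with an estimated correlation (adjusted p = 0.197 and 0.106).

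Between mTEC and cTEC 1038 probe sets were higher and 396 lower by limma, with 2369 at an unadjusted p under 0.05. With the batch block 1763 passed, against 1434. Within-batch differences had a Pearson r of 0.834 across probe sets, and all 1434 called ones, chosen on these arrays, had 1 sign in both. The count was 936 or 946 without cTEC array 1 or 2 and 910 or 860 without mTEC array 1 or 2. Quantile normalisation moved the median of all probe sets by -0.11.

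Dendritic cells, which present antigen in the same medulla, were compared next. Reg3g had a signal of 2366 ± 1116 in mTEC and 4 ± 0.424 in dendritic cells (7.99 ± 0.69), followed among the genes the naming rule admits by Saa3 (7.58 ± 0.77), the keratin Krt17 (7.33 ± 0.81), the carboxylesterase Ces1d (6.92 ± 0.40), Csn2 (6.91 ± 0.55) and Fabp9 (6.87 ± 0.53). Other Krt17 probe sets gave 6.81 ± 0.82, also called, and -0.30 ± 0.49, not called. The myeloid genes Mpeg1 (-5.89 ± 0.45), Plbd1 (-5.37 ± 0.41) and Il1b (-4.83 ± 0.71) and the leukocyte genes Hcls1 (-5.14 ± 0.54), Itgb2 (-4.99 ± 0.45) and Cd48 (-4.98 ± 0.47) were lower in mTEC.

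Among 22 thymic epithelium genes, 18 were higher and 4 did not pass (18 higher adjusted over the list alone, camera adjusted p = 2.16e-11), with the desmosome gene Dsp at 5.66 ± 0.31. Medians were 4.12 and 3.63 within the batches. Among 19 dendritic cell genes, 14 were lower and 5 did not pass (1 higher and 15 lower adjusted over the list alone, camera adjusted p = 7.47e-10), with Itgax (-4.61 ± 0.36) and Ly86 (-4.19 ± 0.43). Medians were -2.42 and -1.90 within the batches. Among 28 cell cycle genes, 24 were lower and 4 did not pass (24 lower adjusted over the list alone, camera adjusted p = 7.39e-15), with the topoisomerase gene Top2a at -3.31 ± 0.45. Medians were -2.20 and -2.03 within the batches. Among 16 MHC class II and costimulation genes, 3 were lower and 13 did not pass (3 lower adjusted over the list alone, camera adjusted p = 0.00915), with Cd83 (-2.91 ± 0.35) and Cd86 (-2.83 ± 0.48). Medians were -0.55 and -0.32 within the batches. Quantile normalisation ended that call (adjusted p = 0.0565). Among 17 medullary epithelium genes, 8 were higher, 1 lower and 8 did not pass (9 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0108, but adjusted p = 0.232 with an estimated correlation), with the transcription factor gene Fezf2 at 6.34 ± 0.61 and Aire at 5.23 ± 0.51. Medians were 1.68 and 0.62 within the batches. Among 25 intestine and stomach genes, 18 were higher and 7 did not pass (20 higher adjusted over the list alone, camera adjusted p = 1.68e-11), with Krt20 (6.49 ± 0.35) and Vil1 (5.05 ± 0.36). Medians were 3.10 and 2.61 within the batches. Among 30 liver and plasma protein genes, 22 were higher and 8 did not pass (23 higher adjusted over the list alone, camera adjusted p = 3.42e-09), with Apoa1 (4.98 ± 0.38) and Apoa4 (6.42 ± 0.55). Medians were 1.98 and 2.07 within the batches. Among 28 skin genes, 22 were higher and 6 did not pass (24 higher adjusted over the list alone, camera adjusted p = 7.82e-11), with Sprr1a (5.64 ± 0.39) and S100a3 (4.16 ± 0.35). Medians were 2.06 and 2.15 within the batches. By camera the cortical epithelium, fibroblast, muscle and nervous system and eye lists were higher (adjusted p = 0.00224, 0.000343, 0.00014 and 1.53e-05). The macrophage and thymocyte lists were lower (adjusted p = 7.23e-05 and 0.00014). Each had medians of 1 sign in both batches. With an estimated correlation none passed (adjusted p = 0.0905, 0.0794, 0.0563, 0.0601, 0.0959 and 0.208).

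Between mTEC and dendritic cells 1562 probe sets were higher and 706 lower by limma, with 3147 at an unadjusted p under 0.05. With the batch block 2714 passed, against 2268. Within-batch differences had a Pearson r of 0.864 across probe sets, and all 2268 called ones, chosen on these arrays, had 1 sign in both. Quantile normalisation moved the median of all probe sets by -0.23 and gave 1262 higher and 898 lower, a share of 58.4% higher instead of 68.9%.

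Against macrophages, the phagocytes of the thymus, the histamine-synthesising enzyme gene Hdc had the largest difference among the genes the naming rule admits (2006 ± 247 against 16.1 ± 18.2, 6.93 ± 0.64), followed by Cldn7 (6.71 ± 0.45), Ces1d (6.42 ± 0.40), Reg3g (6.27 ± 0.69), Csn2 (6.22 ± 0.55) and Krt20 (6.21 ± 0.35). The complement genes C1qb (-6.21 ± 0.75) and C1qa (-5.49 ± 0.36), Mpeg1 (-5.58 ± 0.45), Tspan4 (-5.47 ± 0.46), the macrophage marker Adgre1 (-5.28 ± 0.60) and Entpd1 (-5.25 ± 0.47) were lower in mTEC.

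Among 29 macrophage genes, 1 was higher, 21 lower and 7 did not pass (1 higher and 24 lower adjusted over the list alone, camera adjusted p = 1.4e-17), with the inhibitory receptor Sirpa at -4.65 ± 0.31. Medians were -3.14 and -4.13 within the batches. Among 17 medullary epithelium genes, 14 were higher and 3 did not pass (14 higher adjusted over the list alone, camera adjusted p = 1.11e-08), with Aire at 5.49 ± 0.51. Medians were 3.07 and 3.48 within the batches. Among 19 thymocyte genes, 14 were lower and 5 did not pass (16 lower adjusted over the list alone, camera adjusted p = 2.61e-09, but adjusted p = 0.076 with an estimated correlation), with Cd8b1 (-4.60 ± 0.57) and Cd4 (-2.75 ± 0.35). Medians were -3.57 and -1.52 within the batches. Among 25 intestine and stomach genes, 22 were higher and 3 did not pass (23 higher adjusted over the list alone, camera adjusted p = 3.77e-14), with Vil1 at 4.78 ± 0.36. Medians were 2.15 and 2.65 within the batches. Among 30 liver and plasma protein genes, 20 were higher, 1 lower and 9 did not pass (21 higher and 1 lower adjusted over the list alone, camera adjusted p = 7.53e-08), with Apoa1 (4.99 ± 0.38) and Apoa4 (5.43 ± 0.55). Medians were 1.85 and 2.03 within the batches. Among 21 pancreas genes, 13 were higher, 1 lower and 7 did not pass (16 higher and 1 lower adjusted over the list alone, camera adjusted p = 3.83e-06), with Chgb (5.13 ± 0.42) and Ins2 (5.16 ± 0.50). Medians were 1.14 and 1.81 within the batches. Among 8 salivary and lacrimal gland genes, 5 were higher and 3 did not pass (5 higher adjusted over the list alone, camera adjusted p = 0.00114), with Klk1b22 (4.30 ± 0.34) and Klk1b1 (5.04 ± 0.65). Medians were 2.20 and 1.54 within the batches. Among 34 muscle genes, 16 were higher and 18 did not pass (17 higher adjusted over the list alone, camera adjusted p = 7.85e-07), with Myh4 (5.62 ± 0.39) and Actn3 (4.60 ± 0.42). Medians were 0.91 and 1.54 within the batches. By camera the thymic epithelium and fibroblast lists were higher (adjusted p = 2.56e-07 and 0.0199). So were the MHC class II and costimulation and MHC class I and interferon lists (adjusted p = 0.0391 and 0.0273). The cell cycle list was lower (adjusted p = 1.8e-07). Each had medians of 1 sign in both batches. With an estimated correlation none passed (adjusted p = 0.0606, 0.215, 0.076, 0.0853 and 0.104 in this order). Macrophage array 1 had higher signals than array 2 for 17 of the 22 thymic epithelium genes, with a median log2 difference of 0.83.

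Between mTEC and macrophages 1361 probe sets were higher and 687 lower by limma, with 2969 at an unadjusted p under 0.05. With the batch block 2452 passed, against 2048. Within-batch differences had a Pearson r of 0.792 across probe sets, and all 2048 called ones, chosen on these arrays, had 1 sign in both. Quantile normalisation moved the median of all probe sets by -0.12, and 1360 passed when only these groups were fitted.

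Fabp9, Csn2, Krt20, Vil1, Apoa1, Apoa4, Chgb and Myh4 were higher in mTEC than in cTEC, dendritic cells and macrophages alike. In all 675 probe sets were higher in mTEC than in all 3 other cell types, out of 1038, 1562 and 1361 in the separate comparisons. Independent lists would share 25.4, and simulated unchanged groups compared with the same mTEC arrays shared 265 ± 13 (SD), so part of the excess may come from the shared arrays.

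Dendritic cells and macrophages were compared as the non-epithelial reference. Higher in dendritic cells were the chemokines Ccl17 (930.5 ± 86.1 against 3.35 ± 0.778, 6.84 ± 0.51) and Ccl5 (5.34 ± 0.82), the protease Napsa (6.40 ± 1.09), Tm4sf5 (5.34 ± 0.32), the integrin Itgae (5.27 ± 0.50) and Traf1 (5.27 ± 0.73). Higher in macrophages were the transporter Abcc3 (-5.69 ± 0.50), the transcription factor Spic (-5.42 ± 0.44), Hpgd (-5.29 ± 0.68), Dmpk (-5.10 ± 0.42), Cmbl (-5.04 ± 0.55) and the chemokine Ccl25 (-5.01 ± 0.70). Ccl25 read 1834 and 263 on the macrophage arrays, uneven like epithelial Krt8 (1213 and 172), and 2083 and 3715 in cTEC. Its source was not tested.

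Among 19 dendritic cell genes, 11 were higher and 8 did not pass (13 higher adjusted over the list alone, camera adjusted p = 3.91e-15), including Ccl17. Medians were 2.29 and 2.21 within the batches. Among 29 macrophage genes, 20 were lower and 9 did not pass (21 lower adjusted over the list alone, camera adjusted p = 4.03e-13), with the Fc receptor gene Fcgr1 at -3.59 ± 0.35 and Cd5l at -4.70 ± 0.46. Medians were -1.99 and -2.97 within the batches. Among 16 MHC class II and costimulation genes, 7 were higher and 9 did not pass (11 higher adjusted over the list alone, camera adjusted p = 6.71e-09), with Cd40 (3.48 ± 0.31) and H2-Ob (3.81 ± 0.50). Medians were 1.38 and 1.78 within the batches. Among 20 MHC class I and interferon genes, 9 were higher and 11 did not pass (9 higher adjusted over the list alone, camera adjusted p = 1.25e-06), with Usp18 (2.70 ± 0.29) and Irf7 (1.96 ± 0.33). Medians were 0.75 and 1.21 within the batches. By camera the cortical epithelium, thymic epithelium and thymocyte lists were lower in dendritic cells (adjusted p = 0.000138, 0.000215 and 0.000917). The cell cycle list was higher (adjusted p = 2.84e-07). Each had medians of 1 sign in both batches. With an estimated correlation none passed (adjusted p = 0.104, 0.271, 0.489 and 0.271). Of the 22 thymic epithelium genes, 17 were brighter on macrophage array 1.

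Between dendritic cells and macrophages 338 probe sets were higher and 524 lower by limma, with 1887 at an unadjusted p under 0.05. With the batch block 1190 passed, against 862. Within-batch differences had a Pearson r of 0.67 across probe sets, and all 862 called ones, chosen on these arrays, had 1 sign in both. The count was 566 without dendritic cell array 1 and 180 when only these groups were fitted, and quantile normalisation moved the median of all probe sets by 0.11.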

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

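The tests for dilution, for CD80hi-type cells in the CD80lo gate and for muscle RNA, and the fit without array 1 of both knockout groups, were chosen only after the result was seen. The knockout-label effect differed between CD80hi and CD80lo cells for 121 probe sets in the interaction test. Among the named genes, the log2 change in CD80hi minus that in CD80lo cells was Igf2 -5.90, Acta1 -5.35, Ltf -5.06, Ins2 -4.90, Krt19 -4.70, Gsto1 -4.48, Cck -4.41, Csn1s2a -4.22, Zp3 -4.09, Csn1s1 -3.72, Bpifa2 -3.45, Rbp4 -3.29, Klk6 -3.27, Gip -3.24, Krt6a -3.22, Klk1b22 -3.19, Actc1 -3.12, Apoa1 -3.08, Rhd -2.69, Tnf -2.63, Chgb -2.62 and Ldhc -2.45. The 18S control, outside the comparisons, read 562 on the first knockout CD80hi array and 1893 on the first knockout CD80lo array, above the highest wild-type CD80-sorted array at 376.

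Tissue genes such as Ins2, Csn1s1 and Klk1b22 were lower in CD80hi cells labelled as knockout. Fewer CD80hi-type cells in that gate would have lowered MHC class II and costimulation genes too, but their median change was 0.45 while the median of the lower probe sets was -2.28, which argues against it. An RNA quality difference such as that between the knockout arrays is argued against by the Pearson r of 0.0379 across probe sets between the knockout change in CD80hi cells and the difference of the knockout CD80lo arrays. Without array 1 of both knockout groups 157 probe sets passed, against 284. No test addressed loss of Aire function itself, which stays open together with other differences between the animals or samples of the genotypes.

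Acta1, Meg3, Igf2 and Gsto1 were higher in CD80lo cells labelled as knockout. CD80hi-type cells in that gate are argued against, since the genes raised in wild-type CD80hi cells had a median change of 0.0995, a value that their choice on the shared wild-type CD80lo arrays pushes up (0.41 in simulated unchanged groups). Muscle RNA may contribute and stays open, since the muscle list had a median of 0.741 against 3.55 for Acta1; signals there were 572 for Acta1 and 302 for Actc1; the sort, by markers besides CD80 not given in the sources used here, should remove muscle cells, and 17 of the 34 genes lay above the filter in wild-type CD80lo cells and 0 in another list. A rise of imprinted growth genes as a group, as younger animals might show, also stays open: 4 of 18 others rose and 0 fell at an unadjusted p under 0.05, and their median was 0.217, under the bound of 0.25 set beforehand but by less than its spread. Weighing that spread was decided only after the value was seen.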

How the results depend on the processing

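The split of the shared wild-type CD80hi arrays, the array batch block, the fit without bright probe sets, the fit without array 1 of both knockout groups and the block for the number of the knockout arrays were tests chosen only after the result was seen, as was giving an odds ratio by alternative for the overlap with mTEC-raised probe sets. No named gene or list test reversed under an alternative run, though some called lists had medians of opposite sign between single arrays, as given with them. Total calls, higher plus lower, stayed within 1.5 times of the reported counts under quantile normalisation, no filter, the stricter filter and eBayes without trend. In 4 comparisons each, so did those under the array batch block, the fit without bright probe sets and the knockout array number block. With the smaller constant, 180 probe sets passed between knockout and wild type in CD80hi cells, 18 in CD80lo cells and 44 in the interaction, and 114 were both knockout-lowered and CD80hi-raised. The count shared with mTEC-raised probe sets was also lower by over 1.5 times, while its odds ratio was 45.2 against 48.6. With the larger constant the counts were 47 between genotypes in CD80lo cells and 216 in the interaction. Fits of only the groups compared gave 2456 for wild-type CD80hi against CD80lo, 16 between genotypes in CD80lo cells, 77 in the interaction, 629 for knockout CD80hi against CD80lo, 1360 for mTEC against macrophages and 180 for dendritic cells against macrophages. Without array 1 of both knockout groups, 157 passed between genotypes in CD80hi cells, 44 in the interaction and 532 for knockout CD80hi against CD80lo. With an estimated correlation, the lists that passed numbered 12 for wild-type CD80hi against CD80lo, 1 between genotypes in CD80lo cells, 10 in the interaction, 2 for knockout CD80hi against CD80lo, 12 for mTEC against dendritic cells, 12 against macrophages and 4 for dendritic cells against macrophages. The fry test, which asks whether a list moves and not whether it stands apart, gave 1 list between genotypes in CD80lo cells. With the shared wild-type CD80hi arrays split, 63 and 62 were both knockout-lowered and CD80hi-raised, from fewer arrays in each comparison. The cause of the other shifts was not tested. Keeping 1 gene per family ended the neighbour call for CD80hi-raised genes, at 136 genes with a called neighbour, since members of 1 family no longer count each other.

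Leaving out each array, with the lone array of a group assumed to vary like the others, gave these ranges of counts. They were 626 to 1324 for wild-type CD80hi against CD80lo, 81 to 307 and 8 to 33 between genotypes in CD80hi and CD80lo cells, 34 to 134 in the interaction and 744 to 1353 for knockout CD80hi against CD80lo. The ranges were 860 to 1577, 1554 to 2430 and 1408 to 2105 for mTEC against cTEC, dendritic cells and macrophages, 566 to 858 for dendritic cells against macrophages, 453 to 683 for probe sets higher in mTEC than all 3, and 63 to 214 and 73 to 235 for the overlaps. Shifts over 1.5 times, with the array left out in parentheses, gave 626 (wild-type CD80hi 1), 631 (wild-type CD80hi 2), 681 (wild-type CD80lo 1) and 627 (wild-type CD80lo 2) for wild-type CD80hi against CD80lo. Between genotypes they gave 145 (knockout CD80hi 1), 88 (wild-type CD80hi 1) and 81 (wild-type CD80hi 2) in CD80hi cells and 19 (knockout CD80lo 1), 11 (wild-type CD80lo 1) and 8 (wild-type CD80lo 2) in CD80lo cells. For the interaction they gave 69 (knockout CD80hi 1), 60 (knockout CD80lo 1), 34 (wild-type CD80hi 1), 42 (wild-type CD80hi 2), 68 (wild-type CD80lo 1), 37 (wild-type CD80lo 2), 79 (mTEC 1) and 79 (mTEC 2), and for knockout CD80hi against CD80lo 747 (knockout CD80hi 2) and 744 (knockout CD80lo 1). For mTEC against cTEC they gave 936 (cTEC 1), 946 (cTEC 2), 910 (mTEC 1) and 860 (mTEC 2), for dendritic cells against macrophages 566 (dendritic cell 1), and for the overlaps 100 (knockout CD80hi 1), 63 (wild-type CD80hi 1) and 65 (wild-type CD80hi 2), and 115 (knockout CD80hi 1), 78 (wild-type CD80hi 1) and 73 (wild-type CD80hi 2). Of 357 named gene results, 66 changed a call at least once, among them 19 that no longer passed with the smaller constant, 17 with only the groups compared and 21 without array 1 of both knockout groups. The labels tie no sample number to an animal or day. Of 28 pairs of groups 20 had deviations of same-numbered arrays correlated above 0.1 (0.0265 to 0.526), so numbers were not taken to pair all samples. They went together in the knockout groups (0.517) and on the unfractionated arrays, where all 6 pairs passed 0.1 and the batch block applies. Knockout arrays also went with those of dendritic cells and macrophages (0.335 to 0.383), less with mTEC and cTEC (0.0813 to 0.213). Wild-type sorted ones gave 0.0265 to 0.143, so the genotypes differ here. With the replicate block over all groups 51 probe sets passed between genotypes in CD80lo cells and no other count moved by over 1.5 times. Signal over background limits dim genes most, whose changes the constant of 4.8 compresses.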

Other observations

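Unlike the thymocyte and Y-linked tests, the split of CD80hi-raised genes by their knockout change, the position of unfractionated mTEC, the genes named for the split and the tests by single array were chosen only after the result was seen. All 6 MHC class II and costimulation genes raised in wild-type CD80hi cells, Ctss, Ctsh, H2-Oa, Cd40, Cd86 and the sort marker Cd80, were also raised in knockout CD80hi cells, and their median knockout change was 0.39. All 5 raised salivary and lacrimal gland genes were lower in the knockout samples. Kallikreins of that list (Klk1b22, Klk1b9 and Klk1b1) rested on probes marked as shared with similar sequences, so the 5 may not be independent. Of 16 raised liver and plasma protein genes, 10 were lower in knockout CD80hi cells, while Apoa4, Serpinc1 and Apob were raised there too without being called lower. Of 16 raised intestine and stomach genes 7 were lower and 8 were raised in knockout samples too, including Muc1, Krt20 and Vil1. Of 5 raised mammary gland genes 3 were lower, while the caseins Csn2 and Csn3 were raised in both genotypes. Raised genes were chosen on wild-type CD80hi arrays that the knockout change also uses, which lowers that change. Whether lists differ in these shares was not tested.

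Of the 744 probe sets raised in wild-type CD80hi cells, 202 were lower in knockout CD80hi cells, 325 were raised in the knockout samples too, 21 were both, and 238 neither. Those lower had median signals of 8.65 in wild-type CD80lo and 93.0 in CD80hi cells, and those raised in both genotypes and not lower 33.1 and 213. In unfractionated mTEC, CD80hi-raised probe sets stood at a median of 89.3% of the log2 distance from CD80lo to CD80hi cells, and CD80hi-lowered ones at 72.3%.

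Of 19 thymocyte genes, 14 were higher in both cTEC and macrophages than in mTEC. Cd8b1 read 1253 and 2121 on the cTEC arrays, 2405 and 740.5 on the macrophage arrays and 46.3 and 55.2 on the mTEC arrays, and Dntt 837 and 1902, 789 and 952 and 176 and 174. The median cTEC minus macrophage difference of the 19 genes was -1.02 between the first arrays and 1.30 between the second. Macrophage array 1 also stood above array 2 in epithelial transcripts, named here after their values were seen, with Krt8 at 1213 and 172, Krt17 at 347 and 24.5 and Pax1 at 361 and 91.8.

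Thymocytes or their RNA in both cell samples may explain the thymocyte signals, and this explanation stays open. It needs the genes in 1 ratio between the samples, and the SD over genes of the cTEC minus macrophage difference was 0.431, or 43.2% of the 0.998 over all tested probe sets, under the bound of 50% set beforehand. No single-array version met the bound: the SD was 0.584 against 1.03 on the first arrays, 0.788 against 1.18 on the second, and 0.574 against 0.986 or 0.692 against 1.2 with macrophage array 1 or 2 alone. Of these genes 10 lay above the filter in mTEC and 0 stood in another list. The cells were FACS-sorted by markers not given in the sources used here, so whether the sort removed thymocytes cannot be told.

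Eif2s3y, a Y-linked gene, read 54.3 and 233 on the knockout CD80hi arrays, 36.7 and 149 on the knockout CD80lo arrays and at most 8.2 on any other. Xist, which female cells transcribe, read 25.6 to 62.8 on the knockout, 41.0 to 198.5 on the wild-type sorted and 15.0 to 39.0 on the other arrays. Male animals among the sources of the knockout samples may account for it, as a hypothesis. The only other Y-linked probe set to reach a signal of 20, Uty, differed by a log2 of 0.771 without being higher on every knockout array, so male animals cannot be told apart from another source of Eif2s3y signal with 1 such probe set.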
